A study of Mus musculus with 12 samples.

How the data were processed

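Poly(A) RNA was sequenced from KP cells, a mouse lung adenocarcinoma line. Cells carried either a control guide RNA (written sgCTRL) or a guide RNA against Bach1 (sgBACH1, CRISPR/Cas9 knockout) and were transfected with a control siRNA (siCTRL) or siRNA against Fem1b (siFEM1B) for 48 hours. The 12 libraries form 4 groups of 3, which the design text calls biological replicates; 1 control line and 1 knockout line are named. The libraries were stranded mRNA libraries, per the labels' protocols.

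The deposited table holds whole-number counts per gene symbol, not normalized. The submitters' processing notes list Subread, featureCounts 1.6.4, SAMtools 1.9, DESeq2 1.26.0 and the mouse build mm10, without saying which step each served. The annotation and the strand setting of the counting are not given in the sources used here. The build, tools and annotation affect the values where genes overlap or share near-identical copies. Values of Ftl1, Fth1, Gapdh, Ifitm1, Ifitm3, Prl2c2 and the Sprr genes are therefore uncertain, as are those of the overlapping pairs Rtp4 and Masp1, and Tmem176a and Tmem176b. Coordinates are those of the RefSeq annotation of GRCm38.p6, the assembly that mm10 denotes, and cover the whole gene, exons and introns together. Of the genes tested, 13229 had a position.

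All 24421 gene symbols and all 12 count columns were used; 6056 symbols had no count in any library. Total counts per library ranged from 16539168 to 22196999, so that 1 count was worth 0.0446 to 0.0604 CPM (counts scaled to the total of the library times its TMM factor). Genes were kept with edgeR's filterByExpr at a minimum count of 10, which left 13281. Counts were scaled with TMM factors, which ranged from 0.989 to 1.01. The 20 most abundant genes took 6.16% to 7.12% of the counts. No pair of replicates held identical values, and a chi-square comparison of the counts of replicate pairs gave 2.54 to 14.1 per degree of freedom, so each library was counted as 1 sample.

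Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test. 1 model with a mean for each group was fitted to all 12 libraries, leaving 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. All adjusted p-values of single genes are from this two-sided test unless another tool is named, and n is 3 per group. Log2 fold changes are given with an approximate standard error, and levels as mean CPM with SD. That error is the absolute log2 fold change divided by the square root of the F statistic of the test. The 5 contrasts were knockout against control cells under each siRNA, FEM1B siRNA against control siRNA in each genotype, and the interaction, which is the siRNA effect in knockout cells minus that in control cells. For a group whose libraries were all at 0 the fold is a lower bound against 3 counts over the group. For 1 to 3 counts it is a ratio of summed counts with an exact 95% interval. Intervals and bounds cover counting error only.

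Before the data were examined, the design, the tests, the alternatives, the gene lists and the rule for naming genes were fixed. The rule took, in each contrast, the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 3, no overlap between replicates of the groups compared (not asked of the interaction) and an ordinary gene name. It added up to 4 members with the smallest p of each list, and a fixed set of genes of the pathway that included Bach1, Bach2, Fem1a, Fem1b, Fem1c, Nfe2l2, Keap1, Hmox1, Slc7a11, Gpx4, Fnip1 and Trp53. Some genes that the rule names are not reported here. Which of the rule's genes are given was decided after their values and the results without single libraries were seen. Examples with calls that held were preferred, and some genes with unstable or uncalled values were left out. The 32 lists, written from general knowledge of these pathways and not from these libraries, covered genes described as repressed or activated by BACH1, NRF2 targets, heme synthesis, heme use, iron handling, ferroptosis defence, ferroptosis promotion, the ATF4 stress response, endoplasmic reticulum (ER) chaperones, CUL2 ligase subunits, lysosomal genes of the FLCN and TFE pathway, respiratory chain genes of the nucleus and of the mitochondrial genome, glycolysis, hypoxia targets, cholesterol, fatty acids, epithelial and mesenchymal genes, DNA replication, mitosis, interferon, cytokines of the NF-kB pathway, p53 targets, hedgehog, AP-1, and markers of fibroblasts, leukocytes, endothelium, alveolar type 2 cells and airway or gut lineages. Lists share members, such as Slc7a11. 12 listed symbols were matched through an older or newer symbol, and 26 lists had at least 5 genes kept and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Its p-values were adjusted over the lists of a contrast. Members counted as higher or lower, or above or below 0, are those called, unless given as called or not.

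The pipeline was tested on simulated counts with 200 changed genes among 13281. For the knockout contrast edgeR recovered 85.1%, 95.5% and 100% of genes changed 1.5-, 2- and 4-fold, with 7.43% false calls. For FEM1B siRNA in control cells the shares were 85.1%, 98.5% and 100%, with 5.03% false calls, and for the interaction 65.7%, 92.5% and 100%, with 4.97%. The real contrasts called 807 to 7246 genes, far more than the 200 changed here, so these rates may differ in the real data. For FEM1B siRNA in control cells, camera gave a p of 4.5e-63 for a list of 20 genes raised 1.5-fold, and a p under 0.05 for 3.4% of 500 unchanged lists. The simulated genes varied independently and the lists were random. That share therefore does not show how camera with the preset correlation behaves for lists whose genes vary together.

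The alternatives were DESeq2 1.42.0, limma voom, RLE and upper-quartile factors, no filter, an average log2 CPM of at least 3, the replicate number as a block, only the 6 libraries compared, an adjusted p under 0.01, a fold of at least 2, each library left out, and for lists an estimated correlation and fry. Removal of the median of each chromosome was added after seeing the data. Reads, transcripts, splicing and proteins were not analysed here.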

Results

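RNA was sequenced from mouse KP lung adenocarcinoma cells with BACH1 knocked out, FEM1B knocked down, both or neither. BACH1 is a heme-binding transcriptional repressor and FEM1B a substrate receptor of the CUL2 ubiquitin ligase. The question was how each affects genes related to ferroptosis, an iron-dependent form of cell death. The 4 groups were control and BACH1 knockout cells, each with control siRNA or FEM1B siRNA for 48 hours, with 3 biological replicates each per the design text. Total counts per library lay between 19885927 and 21863058 in control cells with control siRNA and between 19189574 and 21719512 in knockout cells with control siRNA. With FEM1B siRNA they lay between 18530571 and 22196999 in control cells and between 16539168 and 20474719 in knockout cells. The first principal component of log2 CPM held 67.2% of the variance and separated the genotypes, and the next separated the siRNAs.

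Fem1b (chromosome 9, 62791824 to 62811648, mm10) was measured at 157 to 167 CPM in the 3 libraries of control cells with control siRNA and at 43.0 to 58.0 CPM with FEM1B siRNA. In knockout cells it was at 136 to 141 CPM with control siRNA and 46.2 to 54.5 CPM with FEM1B siRNA. Fem1b fell by 1.66 ± 0.08 on the log2 scale in control cells (adjusted p = 2.77e-11) and by 1.51 ± 0.08 in knockout cells (adjusted p = 1.66e-10). Bach1 (chromosome 16, 87698954 to 87733346) was at 31.4 ± 2.04 CPM in control cells and 29.5 ± 1.72 CPM in knockout cells with control siRNA, a log2 fold change of −0.09 ± 0.08 (adjusted p = 0.344). With FEM1B siRNA its levels were 41.4 ± 3.25 and 39.9 ± 0.601 CPM, a log2 fold change of −0.05 ± 0.08 (adjusted p = 0.575). A CRISPR lesion need not lower the transcript it hits, so Bach1 counts on their own check nothing about the knockout. Bach1 rose with FEM1B siRNA, by 0.40 ± 0.08 in control cells (adjusted p = 0.000242) and 0.44 ± 0.08 in knockout cells (adjusted p = 0.000133).

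**Figure D1:**
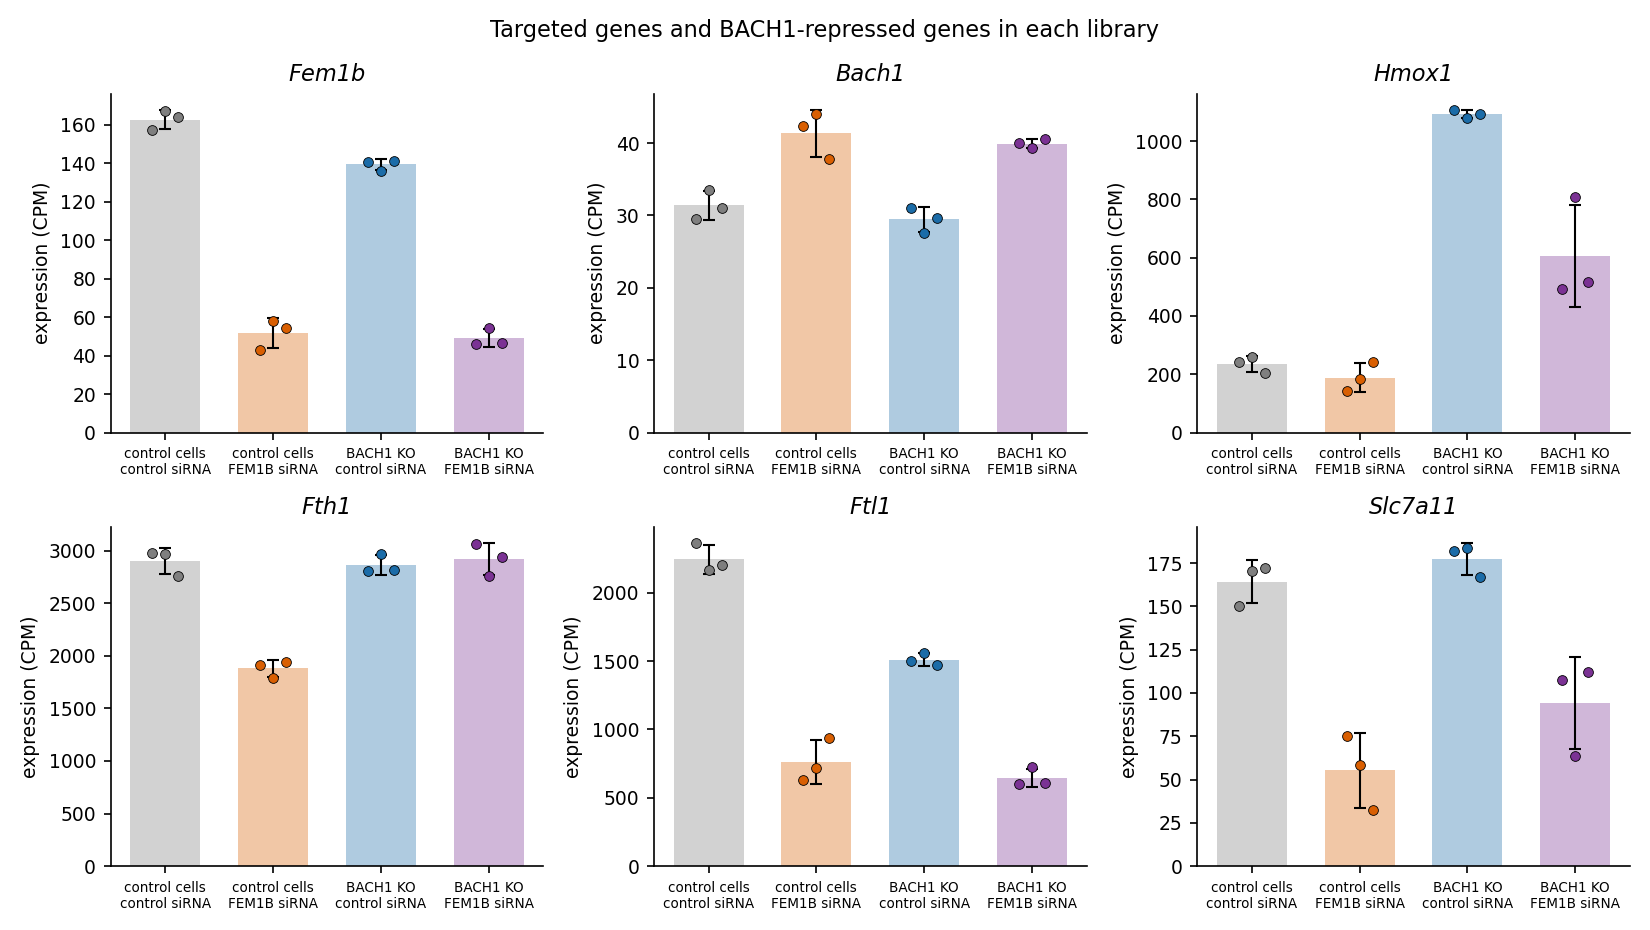
CPM (linear axes) of Fem1b, Bach1, Hmox1, Fth1, Ftl1 and Slc7a11 in the 4 groups; bars are means, error bars SD and points the 3 replicates. Fem1b lay at or below 58.0 CPM in all 6 libraries with FEM1B siRNA and at or above 136 CPM in the other 6.

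Loss of BACH1 was first examined under control siRNA. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1 and is a classical BACH1 target (chromosome 8, 75093618 to 75100593), rose from 235 ± 28.2 to 1093 ± 13.8 CPM, a log2 fold change of 2.22 ± 0.16 (adjusted p = 6.24e-10). Interferon-stimulated genes were lower in knockout cells: all 21 measured members of the list fell, with a median log2 fold change of −3.50. They lie on 13 chromosomes, and the median was −3.55 with the median of each chromosome removed, a setting chosen after seeing the data. Rsad2 changed by −6.54 ± 0.33, Ifit1 by −4.44 ± 0.21 and Oasl2 by −4.29 ± 0.20. Genes described as repressed by BACH1, Hmox1 included, went both ways, with 3 of 18 members called higher and 10 lower. Slc7a11, the cystine transporter subunit, and Gpx4, the lipid peroxide reductase, were not called in this contrast, with log2 fold changes of 0.11 ± 0.19 (adjusted p = 0.649) and 0.12 ± 0.08 (adjusted p = 0.229). A fit to the 6 libraries compared called both, with adjusted p = 0.0447 for Slc7a11 and 0.0473 for Gpx4.

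In total 6702 of 13281 genes were called, 3210 higher and 3492 lower in knockout cells, and 712 and 532 of these changed at least 2-fold. The replicates of the groups did not overlap for 8011 genes, or 60.3%, where chance gives 10%. Several genes had counts in knockout cells alone among these groups. Fyn, a Src-family kinase, was at 41.2 ± 2.1 CPM in knockout cells and 0 in control cells, at least 866-fold higher; Sox12 was at least 524-fold and Acsl6 at least 397-fold higher. Smoc2 was 616-fold higher by the ratio of counts (95% interval 170 to 5089). Creb3l1 rose by 6.80 ± 0.24, Camk4 by 6.24 ± 0.22 and Pmaip1 by 6.24 ± 0.27. Serpinh1, a collagen chaperone, rose from 3.34 ± 0.523 to 232 ± 7.27 CPM, a log2 fold change of 6.11 ± 0.09 (adjusted p = 1.13e-20). The largest falls by the naming rule were those of Nlrc5, a regulator of MHC class I genes, at −7.91 ± 0.27, and of Rsad2, Aqp8 (−6.52 ± 0.24), Sprr2h (−5.60 ± 0.19), Ifitm1 (−5.55 ± 0.15), Rtp4 (−5.04 ± 0.21), Sprr1a (−4.67 ± 0.11) and Slfn2 (−4.60 ± 0.11).

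Expression also shifted by whole chromosomes between the cell lines. The median log2 fold change of knockout against control cells was 0.44 on chromosome 19, 0.27 on chromosome 9, 0.24 on chromosome 14 and −0.28 on chromosome 12. The SD of the 20 chromosome medians was 0.169 in this contrast, against 0.0240 for FEM1B siRNA in control cells. With the chromosome medians removed 5834 genes were called. Fem1b itself was lower in knockout cells under control siRNA, at −0.22 ± 0.08 (adjusted p = 0.0241). That call ended without replicate 2 or 3 of sgCTRL_siCTRL (adjusted p = 0.0783 and 0.0622) and without replicate 1 or 2 of sgBACH1_siCTRL (0.0536 and 0.0713).

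**Figure D2:**
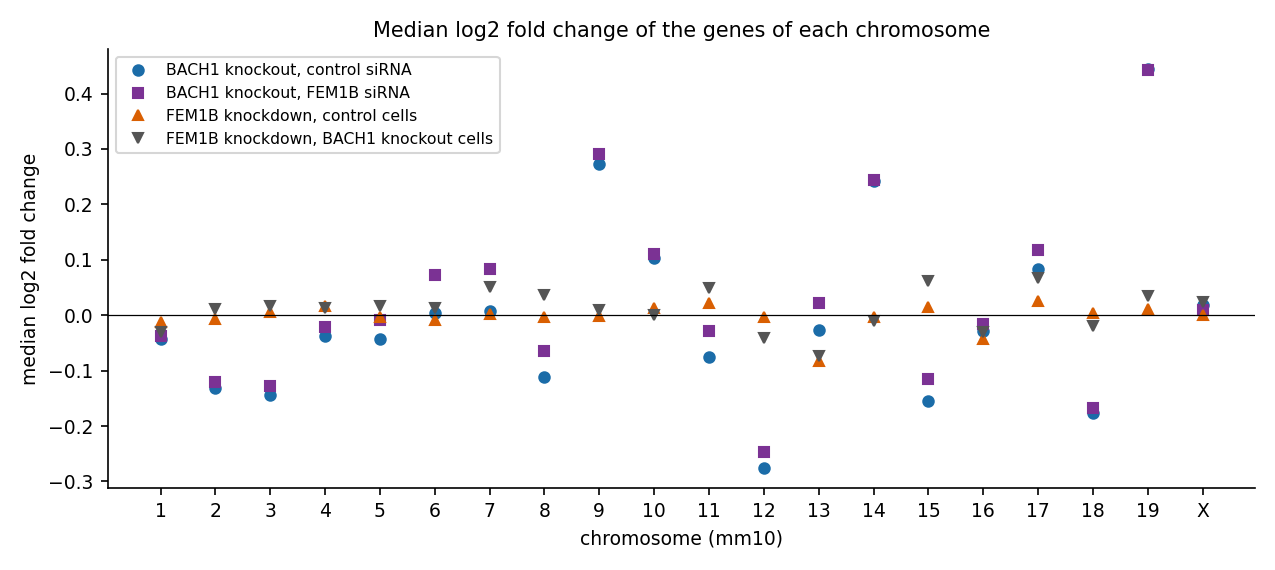
Median log2 fold change of the genes on each of the 20 chromosomes (horizontal axis) in the 4 contrasts between groups; each point is 1 chromosome median. Chromosome 19 lay at 0.44 in both knockout contrasts, while the medians of the knockdown contrasts stayed within −0.08 and 0.07.

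Among the gene lists in this contrast, the interferon list was called (adjusted p = 2.59e-13; adjusted p = 0.0672 with an estimated correlation). Of the list of BACH1-repressed genes, Hmox1 rose while Osgin1 fell by 1.57 ± 0.07, Abcb6 by 0.83 ± 0.09 and Srxn1 by 0.69 ± 0.06; the list test gave adjusted p = 0.115. Of 7 genes described as activated by BACH1, 1 rose (Gapdh) and 3 fell, among them Spp1 by 0.54 ± 0.07 (list adjusted p = 0.606). NRF2 targets had 6 of 30 members called higher and 13 lower (adjusted p = 0.161), with the microsomal glutathione transferase Mgst1 at −3.19 ± 0.10. Nfe2l2, which encodes NRF2, was at −0.06 ± 0.06 (adjusted p = 0.377), and at 0.07 with the chromosome medians removed (adjusted p = 0.38). Ferroptosis defence genes had 8 of 35 called higher, such as Cth (1.58 ± 0.15), and 14 lower (adjusted p = 0.619), and ferroptosis-promoting genes 10 of 29 called higher, such as Elovl5 (0.66 ± 0.05), and 4 lower, such as Ptgs2 (−0.74 ± 0.09; list adjusted p = 0.279). In iron handling, 7 of 24 rose and 10 fell (adjusted p = 0.851), with the metal transporter Slc39a8 at 1.38 ± 0.12 and ceruloplasmin, Cp, at −3.18 ± 0.26. In heme synthesis 2 of 11 rose, among them Slc25a38 (0.94 ± 0.14), and 3 fell (adjusted p = 0.926). In heme use 3 of 11 rose and 5 fell (adjusted p = 0.851), and Pgrmc1, a heme-binding protein, was at 7.86 ± 0.666 CPM against 0, at least 166-fold higher.

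The remaining lists were not called in knockout cells under control siRNA. Lysosomal genes had 3 of 25 members called higher and 15 lower (adjusted p = 0.115), with Ctsl at −0.60 ± 0.05 and Ppargc1a at −1.06 ± 0.14. Cytokine genes of the NF-kB list had 11 of 16 called higher and 3 lower (adjusted p = 0.0605), with Cxcl5 at 1.82 ± 0.10 and Csf3 at −2.55 ± 0.24. Of the ATF4 response, 8 of 25 rose and 8 fell (adjusted p = 0.431), and Stc2 was at least 103-fold higher. Of the ER chaperones, 7 of 16 rose and the rest were not called (adjusted p = 0.212), with Manf at 0.84 ± 0.08 and Hspa5 at 0.61 ± 0.13. Glycolysis had 11 of 20 called higher and 2 lower (adjusted p = 0.109), hypoxia targets 9 of 16 and 2 (0.115), cholesterol genes 9 of 20 and 1 (0.115), and fatty acid genes 8 of 15 and 2 (0.115). Epithelial genes had 4 of 12 called higher, such as Dsp (4.46 ± 0.48), and 6 lower, such as Krt7 (−1.96 ± 0.06; list adjusted p = 0.606). Mesenchymal genes had 9 of 18 called higher, such as Twist1 (2.89 ± 0.17), and 4 lower (list adjusted p = 0.547). The counts of called genes were 14 higher and 6 lower of 49 nuclear respiratory chain genes (adjusted p = 0.342), 6 and 1 of 20 replication genes (0.242) and 9 and 4 of 20 mitosis genes (0.473). They were 3 and 5 of 17 CUL2 ligase genes (0.988), 4 and 4 of 13 p53 targets (0.851), 2 and 3 of 5 hedgehog genes (0.988) and 6 and 4 of 16 AP-1 genes (0.606). Adjusted over the list alone, the counts were the same except 4 higher and 6 lower for heme use and 14 and 4 for the respiratory chain. The median, mean and test differed in sign for heme synthesis, heme use, CUL2 ligase, epithelial genes and p53 targets. Genes without counts in a group lay at the end of their list, so their bounds leave the medians as they are.

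FEM1B siRNA in control cells was compared with control siRNA to measure the effect of FEM1B knockdown where Bach1 was not targeted. The knockdown was partial, with Fem1b left at 43.0 to 58.0 CPM. Off-target effects of the siRNA were not tested and cannot be told apart from those of lower Fem1b. The ferritin light chain gene Ftl1 fell from 2244 ± 105 to 761 ± 160 CPM, a log2 fold change of −1.56 ± 0.10 (adjusted p = 5.43e-10), and the ferritin heavy chain gene Fth1 fell by 0.62 ± 0.05 (adjusted p = 2.15e-08). Slc7a11 (chromosome 3, 50364936 to 50499087) fell from 164 ± 12.3 to 55.3 ± 21.6 CPM, a log2 fold change of −1.56 ± 0.20 (adjusted p = 2.94e-06). The transcript of NRF2 itself, Nfe2l2, fell from 116 ± 0.788 to 55.3 ± 3.15 CPM (adjusted p = 1.07e-10). Hmox1 was not called, at −0.32 ± 0.16 (adjusted p = 0.113), but was called without replicate 3 of sgCTRL_siFEM1B (0.00927) or replicate 2 of sgBACH1_siFEM1B (0.0278).

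Both lists of antioxidant and iron genes that BACH1 and NRF2 are described to control were called lower. The lists share many members, such as Slc7a11, Gclc, Gclm, Nqo1, Txnrd1 and Osgin1, so the calls are not separate results. The list of NRF2 targets as fixed also holds Nfe2l2 itself and Keap1. Of the BACH1-repressed genes 10 of 18 fell and 2 rose, with a median of −0.32 (adjusted p = 0.00492; adjusted p = 0.175 with an estimated correlation). Of the NRF2 targets 16 of 30 fell and 2 rose, with a median of −0.18 (adjusted p = 0.00272; adjusted p = 0.137 with an estimated correlation); Pgd fell by 0.51 ± 0.05 and Osgin1 by 0.72 ± 0.07. Ferroptosis defence genes had 15 of 35 members called lower, among them Slc7a11, Nfe2l2 and Prdx6 (−0.76 ± 0.06), and 6 higher, and the list was not called (adjusted p = 0.0918). Of ferroptosis-promoting genes 10 of 29 fell, such as Ptgs2 (−0.78 ± 0.09), and 3 rose, such as Tmem189 (0.65 ± 0.09; list adjusted p = 0.397). Iron handling had 8 of 24 called lower, such as Cisd2 (−0.70 ± 0.07), and 2 higher; 8 members were called adjusted over the list alone, all lower (list adjusted p = 0.397). Heme synthesis had 4 of 11 called lower, with Uros at −0.95 ± 0.19 and Cpox at −0.38 ± 0.08 (list adjusted p = 0.413). Heme use had 5 of 11 called higher, such as Abcb6 (0.56 ± 0.08), and 3 lower, such as Abcg2 (−0.92 ± 0.15; list adjusted p = 0.98).

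Other lists were called in control cells with FEM1B siRNA. Of the ATF4 response 15 of 25 genes fell and 3 rose (17 and 3 adjusted over the list alone), with a median of −0.37 (adjusted p = 0.0197; adjusted p = 0.575 with an estimated correlation); the serine synthesis enzyme Phgdh fell by 0.83 ± 0.08 and Shmt2 by 0.76 ± 0.10. Hypoxia targets rose in 14 of 16 members and fell in 2, with a median of 0.46 (adjusted p = 0.00334; adjusted p = 0.575 with an estimated correlation), as for Ndrg1 at 0.67 ± 0.10 and Mxi1 at 0.53 ± 0.07. ER chaperones rose in 10 of 16 members, median 0.22 (adjusted p = 0.00557; adjusted p = 0.575 with an estimated correlation), as for Manf at 0.71 ± 0.08 and Edem1 at 0.55 ± 0.06. Cholesterol genes rose in 11 of 20 members (13 adjusted over the list alone), median 0.24 (adjusted p = 0.00334; adjusted p = 0.575 with an estimated correlation), as for Hmgcs1 at 0.90 ± 0.07; the median was 0.16 without replicate 1 of sgCTRL_siFEM1B. Lysosomal genes rose in 13 of 25 and fell in 2 (14 and 2 adjusted over the list alone), median 0.16 (adjusted p = 0.00334; adjusted p = 0.337 with an estimated correlation), as for Neu1 at 1.04 ± 0.08 and Flcn at 0.52 ± 0.07. Interferon genes rose in 14 of 21 (15 adjusted over the list alone), median 0.54 (adjusted p = 0.00272; adjusted p = 0.337 with an estimated correlation), as for Irf7 at 1.08 ± 0.13 and Bst2 at 0.79 ± 0.08.

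Respiratory chain and glycolysis genes were called with smaller shifts. Of the nuclear respiratory chain genes 19 of 49 rose and 2 fell, median 0.13 (adjusted p = 0.033; adjusted p = 0.667 with an estimated correlation), with Uqcrh at 0.50 ± 0.07. That call ended without replicate 2 or 3 of sgCTRL_siCTRL (adjusted p = 0.0847 and 0.0722) and without replicate 3 of sgCTRL_siFEM1B (0.137, median 0.08), and fry gave adjusted p = 0.108. Of the glycolysis genes 7 of 20 rose and 1 fell, median 0.14 (adjusted p = 0.0355; adjusted p = 0.593 with an estimated correlation), with Aldoc at 0.73 ± 0.09. This call ended without replicate 2 of sgCTRL_siCTRL (0.0847) and replicate 3 of sgCTRL_siFEM1B (0.102, median 0.08), and among genes with an average log2 CPM of at least 3 (0.085).

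The genes with the largest changes by the naming rule in control cells with FEM1B siRNA included several outside these lists. Apoc2, an apolipoprotein gene, rose from 1.77 ± 0.0658 to 12.2 ± 0.453 CPM, a log2 fold change of 2.77 ± 0.13 (adjusted p = 1.68e-11). Tspan1 rose by 2.28 ± 0.17, Adap1 by 2.02 ± 0.13, Dmpk by 1.96 ± 0.11, Hs3st1 by 1.95 ± 0.14, Sprr1a by 1.77 ± 0.09, Mpzl2 by 1.70 ± 0.15 and Cd82 by 1.62 ± 0.09. Cyp1b1, a cytochrome P450 gene, fell by 1.93 ± 0.07, Masp1 by 1.84 ± 0.15, Dynlt3 by 1.59 ± 0.07, Syt12 by 1.53 ± 0.13 and Prl2c2 by 1.46 ± 0.13. Of 13281 genes 5981 were called, 2940 higher and 3041 lower, of which 385 and 156 changed at least 2-fold. Replicates did not overlap for 6920 genes, or 52.1%, where chance gives 10%.

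The lists not called in this contrast held single genes that changed. The macrophage-associated gene Cd68 rose by 1.58 ± 0.14; the other 10 leukocyte markers were not kept, having under 10 counts in every library. The cell cycle inhibitor Cdkn1a rose by 1.28 ± 0.11 while 6 of 13 p53 targets fell and 2 rose (list adjusted p = 0.397). Fos rose by 1.62 ± 0.15 among AP-1 genes, of which 8 of 16 rose and 2 fell (0.0677). Snai2 fell by 1.38 ± 0.13 among mesenchymal genes, of which 9 of 18 fell and 5 rose (0.397), and Cldn4 rose by 1.41 ± 0.19 among epithelial genes, of which 6 of 12 rose and 2 fell (0.0918). The counts of called genes were 4 higher and 1 lower of 7 BACH1-activated genes (0.397), 5 and 4 of 15 fatty acid genes (0.397), 4 and 1 of 20 replication genes (0.486), and 9 and 2 of 20 mitosis genes (0.0918). They were 5 and 5 of 16 cytokine genes (0.46), 5 and 3 of 17 CUL2 ligase genes (0.804) and 1 and 3 of 5 hedgehog genes (0.397). Adjusted over the list alone the counts in this contrast were the same, except those given above, 5 higher and 10 lower for mesenchymal genes, and 10 and 2 for mitosis genes. The median, mean and test differed in sign for heme use, iron handling, CUL2 ligase, cytokine and hedgehog genes.

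**Figure D3:**
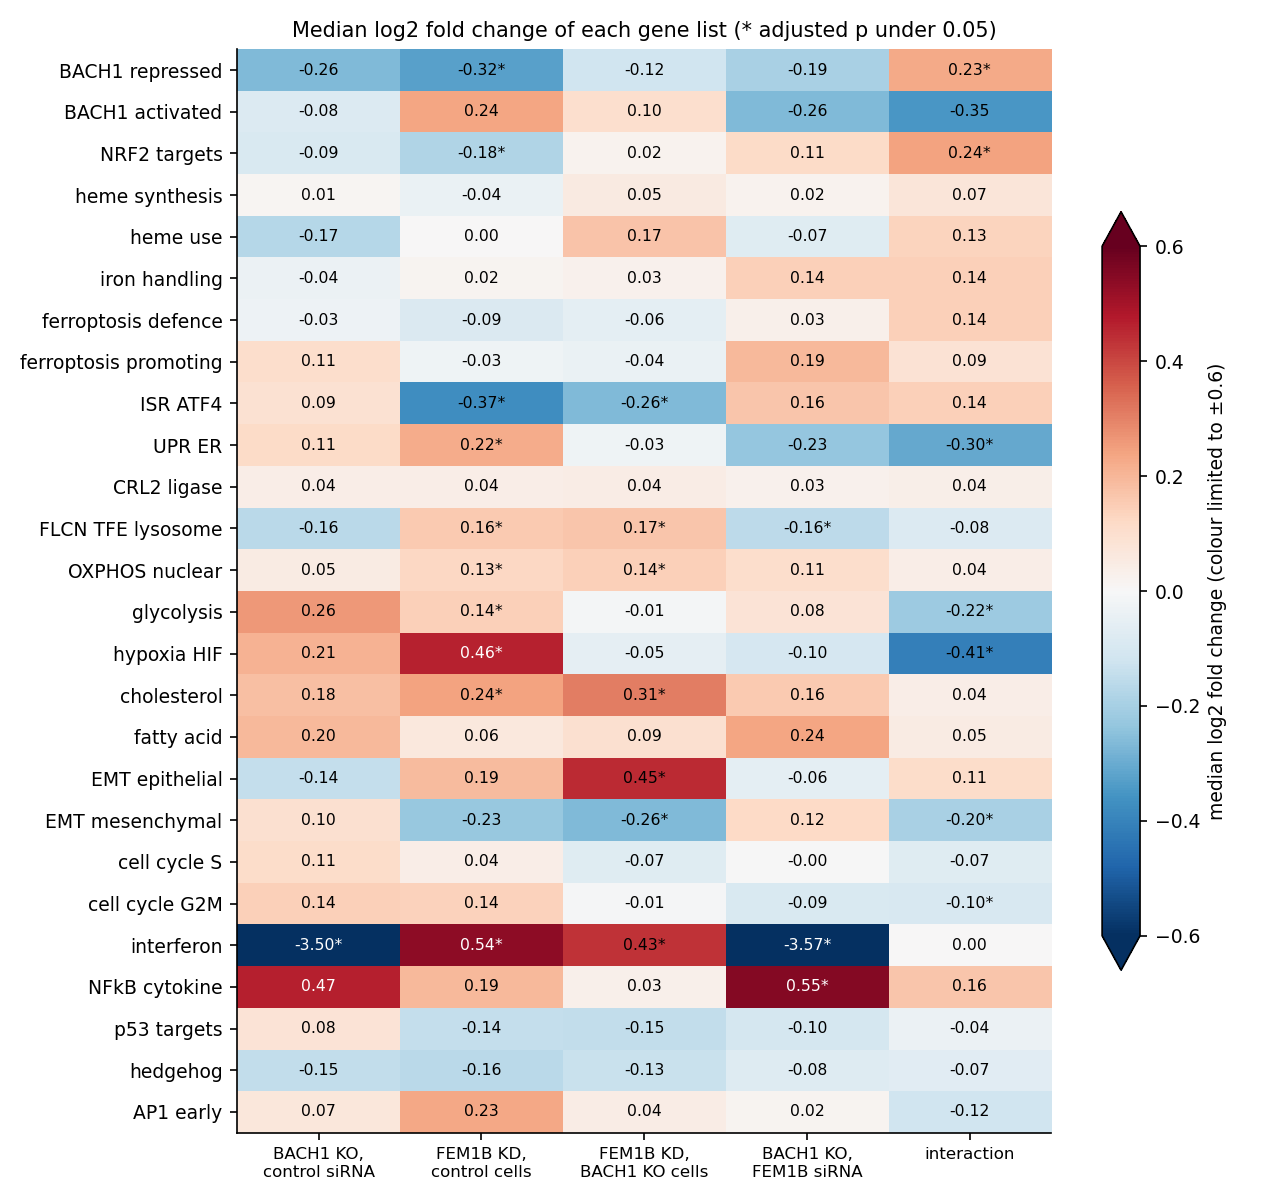
Median log2 fold change (colour, limited to 0.6 on either side of 0) of 26 gene lists (vertical axis) in the 5 contrasts (horizontal axis); an asterisk marks an adjusted p under 0.05 by camera with the preset correlation. With an estimated correlation 1 of the 28 calls remained, that of NRF2 targets in the interaction.

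The question of whether FEM1B siRNA acts alike without BACH1 was addressed in knockout cells. Ftl1 fell there by 1.23 ± 0.10 (adjusted p = 1.84e-08), Slc7a11 by 0.91 ± 0.19 (adjusted p = 0.000762), Nfe2l2 by 0.93 ± 0.06 (adjusted p = 9.72e-10) and Hmox1 by 0.85 ± 0.16 (adjusted p = 0.000196). Fth1 was at 2866 ± 93.5 CPM with control siRNA and 2921 ± 151 CPM with FEM1B siRNA. Apoc2 rose by 5.49 ± 0.17, Tspan1 by 3.72 ± 0.33, Adap1 by 3.38 ± 0.20, Hs3st1 by 2.67 ± 0.12, Aqp8 by 2.59 ± 0.38, Glod5 by 2.17 ± 0.13, Ifitm3 by 2.14 ± 0.21 and Smpd3 by 2.10 ± 0.12. Masp1 fell by 1.87 ± 0.21, Sspn by 1.55 ± 0.10, Ctgf by 1.52 ± 0.17, Thbs1 by 1.44 ± 0.16, Shroom4 by 1.37 ± 0.21, Dynlt3 by 1.34 ± 0.06 and Cyp1b1 by 1.30 ± 0.08. Ctgf and Thbs1 are known YAP and TGF-beta responsive genes. In all 5539 genes were called, 2915 higher and 2624 lower, of which 386 and 121 changed at least 2-fold, and replicates did not overlap for 6844 genes, or 51.5% (10% by chance).

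In knockout cells 7 lists were called with FEM1B siRNA. Of the cholesterol genes 13 of 20 rose, median 0.31 (adjusted p = 0.00306; adjusted p = 0.728 with an estimated correlation), with Hmgcs1 at 0.76 ± 0.07 and Fdft1 at 0.61 ± 0.07. Of the respiratory chain genes 24 of 49 rose and 2 fell (24 and 3 adjusted over the list alone), median 0.14 (adjusted p = 0.00636; adjusted p = 0.931 with an estimated correlation). Of the lysosomal genes 13 of 25 rose and 3 fell, median 0.17 (adjusted p = 0.0147; adjusted p = 0.596 with an estimated correlation), with Tfeb at 0.70 ± 0.09. Of the interferon genes 13 of 21 rose, median 0.43 (adjusted p = 0.00636; adjusted p = 0.596 with an estimated correlation), with Oasl2 at 1.51 ± 0.27; the median was 0.73 without replicate 3 of sgBACH1_siCTRL. Of the mesenchymal genes 11 of 18 fell, median −0.26 (adjusted p = 0.00636; adjusted p = 0.596 with an estimated correlation), with Zeb2 at −0.74 ± 0.09. Of the epithelial genes 8 of 12 rose, median 0.45 (adjusted p = 0.00636; adjusted p = 0.596 with an estimated correlation), with Dsp at 1.89 ± 0.24 and Jup at 0.69 ± 0.05. The epithelial call ended among genes with an average log2 CPM of at least 3 (adjusted p = 0.144). Of the ATF4 response 12 of 25 fell and 2 rose, median −0.26 (adjusted p = 0.00636; adjusted p = 0.728 with an estimated correlation), with Aldh1l2 at −0.74 ± 0.07; without replicate 2 of sgBACH1_siFEM1B the median was −0.16 and the adjusted p 0.0662.

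BACH1-repressed genes were not called as a list in knockout cells with FEM1B siRNA: 8 of 18 fell and 5 rose (adjusted p = 0.433). NRF2 targets had 8 of 30 called lower and 9 higher (8 and 10 adjusted over the list alone; list adjusted p = 0.994), with Idh1 at 0.62 ± 0.07 and Prdx1 at 0.56 ± 0.05. Ferroptosis defence genes had 11 of 35 called lower, such as Prdx6 (−0.44 ± 0.06), and 7 higher, such as Hspb1 (1.33 ± 0.13; list adjusted p = 0.667). ER chaperones had 5 of 16 called lower, such as Hyou1 (−0.32 ± 0.06), and 1 higher (adjusted p = 0.611), and hypoxia targets had 3 of 16 called lower, such as Pdk1 (−0.48 ± 0.07), and 2 higher (adjusted p = 0.667). Counts adjusted over the list alone were the same for the lists in this and the last paragraph where no others are given. The median, mean and test differed in sign for BACH1-activated, heme synthesis, iron handling, CUL2 ligase, glycolysis and mitosis genes.

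Across all genes the log2 fold changes of FEM1B siRNA in the 2 genotypes, which share no library, correlated with Pearson r = 0.628 and Spearman rho = 0.635. Genes are not independent replicates, and 3 such relations were computed. Genes higher in both numbered 1817 and genes lower in both 1786, where independent lists would share 645 and 601; 30 and 40 genes were called in opposite directions. The changes with BACH1 knockout and with FEM1B siRNA, which share the 3 libraries of control cells with control siRNA, correlated with r = 0.133 and rho = 0.164. Unchanged groups simulated against those controls gave r = 0.493. The covariance was 0.0796, against 0.0275 in the simulations, a difference of 0.0521. Genes higher in both numbered 923 and genes lower in both 1134, where independent lists would share 711 and 800. Genes higher with knockout and lower with FEM1B siRNA numbered 504 (735 if independent), and the reverse 761 (773 if independent). Part of the excess may come from the shared controls.

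Knockout and control cells were compared again under FEM1B siRNA. Hmox1 was at 606 ± 175 CPM in knockout and 189 ± 49.6 CPM in control cells, a log2 fold change of 1.69 ± 0.16 (adjusted p = 3.4e-08). Here Slc7a11 was higher by 0.76 ± 0.20 (adjusted p = 0.00303), or by 0.48 without replicate 3 of sgCTRL_siFEM1B. Fth1 was higher by 0.64 ± 0.05 (adjusted p = 5.8e-09) and Gclm, a subunit of the glutathione synthesis enzyme, by 0.78 ± 0.06 (adjusted p = 3.8e-09). Sox12 was at least 366-fold and Fyn 759-fold higher by the ratio of counts (95% interval 259 to 3682); Pgrmc1 was at least 180-fold and Stc2 at least 62.4-fold higher. Acsl6 was higher by 8.09 ± 0.31, Smoc2 by 6.53 ± 0.29, Serpinh1 by 6.30 ± 0.09, Camk4 by 5.94 ± 0.25, Ptpru by 5.75 ± 0.13 and Pmaip1 by 5.64 ± 0.24. Rsad2 was lower at −6.78 ± 0.33, Nlrc5 at −6.28 ± 0.22, Sprr2h at −4.99 ± 0.17, Slfn2 at −4.60 ± 0.12, Rtp4 at −4.54 ± 0.18, Sprr1a at −4.37 ± 0.10, Tmem176b at −4.10 ± 0.09 and Tmem176a at −4.02 ± 0.11. In all 7246 genes were called, 3741 higher and 3505 lower, of which 773 and 547 changed at least 2-fold, and replicates did not overlap for 7564 genes, or 57.0% (10% by chance). The shifts by chromosome were present here too, with a median of 0.44 on chromosome 19 and −0.25 on chromosome 12, and 6613 genes were called with the chromosome medians removed. The changes with knockout under the 2 siRNAs correlated with r = 0.918 and rho = 0.772 across genes; 2476 genes were higher and 2477 lower in both, where independent lists would share 904 and 922.

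Under FEM1B siRNA 3 lists were called between the genotypes. All 21 interferon genes were lower in knockout cells, median −3.57 (adjusted p = 1.65e-13; adjusted p = 0.0643 with an estimated correlation), with Usp18 at −5.36 ± 0.25 and Irf7 at −3.67 ± 0.17. Of the lysosomal genes 16 of 25 were called lower and 3 higher, median −0.16 (adjusted p = 0.0382; adjusted p = 0.609 with an estimated correlation), with Atp6v1a at −0.67 ± 0.07 and Lamp1 at −0.31 ± 0.05; among genes with an average log2 CPM of at least 3 the adjusted p was 0.0799. Of the cytokine genes 12 of 16 were called higher and 3 lower, median 0.55 (adjusted p = 0.0416; adjusted p = 0.856 with an estimated correlation), with Cxcl5 at 2.28 ± 0.10 and Icam1 at 0.77 ± 0.07. The cytokine call ended with the replicate number as a block (0.0546), among genes with an average log2 CPM of at least 3 (0.0838), and without replicate 3 of sgCTRL_siCTRL (0.0519), replicate 1 of sgBACH1_siCTRL (0.0525) or replicate 2 of sgCTRL_siFEM1B (0.0544). Of the BACH1-repressed genes 6 of 18 were called higher and 8 lower (adjusted p = 0.717), with a median of −0.19 and a mean of 0.00 (above 0) while the test pointed below 0. NRF2 targets had 14 of 30 called higher and 8 lower (adjusted p = 0.551). Ferroptosis defence genes had 13 of 35 called higher, such as Cth (2.02 ± 0.17), and 10 lower, such as Mgst1 (−2.84 ± 0.10; list adjusted p = 0.96), and ferroptosis-promoting genes had 15 of 29 called higher, such as Yap1 (0.56 ± 0.06), and 5 lower, such as Atf3 (−0.77 ± 0.09; list adjusted p = 0.161). Adjusted over the list alone the counts of these lists were the same, except 16 and 5 for ferroptosis promotion. The median, mean and test also differed in sign for heme use, CUL2 ligase, epithelial, mesenchymal, replication and AP-1 genes.

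The interaction tested whether the effect of FEM1B siRNA differed between the control line and the knockout line. With 1 line of each, a difference cannot be assigned to BACH1 rather than to other differences between the lines. NRF2 targets had higher interaction values: 7 of 30 members were called, all above 0 (9 adjusted over the list alone), with a median of 0.24 (adjusted p = 2.49e-06; adjusted p = 0.02 with an estimated correlation). Osgin1 had an interaction of 1.11 ± 0.10 (adjusted p = 8.18e-06), Gsta4 of 0.94 ± 0.11 (5.97e-05), Gstm1 of 0.70 ± 0.12 (0.00212) and Idh1 of 0.56 ± 0.09 (0.0018). Fth1 fell with FEM1B siRNA in control cells, and its interaction was 0.65 ± 0.08 (adjusted p = 5.97e-05). Hspa5, an ER chaperone, had an interaction of −0.83 ± 0.18 (adjusted p = 0.0108) and Ndrg1, a hypoxia target, of −0.83 ± 0.15 (adjusted p = 0.00269).

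In the interaction 807 of 13281 genes were called, 462 above and 345 below 0, of which 51 and 39 by at least 2-fold. The share above 0 was 57.2%, and other settings turned the majority: it was 45.6% of 810 genes with RLE factors, 44.2% of 1091 in DESeq2, 39.2% of 872 among genes with an average log2 CPM of at least 3, and 41.9% of 1002 without replicate 3 of sgCTRL_siFEM1B. Of the 807 genes 333 were called for FEM1B siRNA in control cells alone, 233 in knockout cells alone, 169 in both in the same direction, 70 in both in opposite directions and 2 in neither. The count was 386 without replicate 3 of sgCTRL_siCTRL, 298 and 305 without replicates 1 and 3 of sgBACH1_siCTRL, 396 without replicate 2 of sgCTRL_siFEM1B, and 297, 1859 and 299 without replicates 1, 2 and 3 of sgBACH1_siFEM1B. The largest positive values by the naming rule that held without any 1 library were those of Aqp8 (2.94 ± 0.40), Apoc2 (2.71 ± 0.26), Cldn2 (2.55 ± 0.31), Ifitm1 (1.58 ± 0.22), Hsd17b14 (1.55 ± 0.18), Acaa1b (1.46 ± 0.24) and Ifitm3 (1.45 ± 0.24). Aqp8 and Ifitm1 were among the largest falls in knockout cells under control siRNA. Their siRNA effects there thus start from a much lower level than in control cells. Ero1l, an ER oxidase induced by hypoxia, was at 929 ± 123 CPM and 1453 ± 272 CPM in control cells with control and FEM1B siRNA, and at 1059 ± 86.7 and 708 ± 292 CPM in knockout cells, an interaction of −1.23 ± 0.25 (adjusted p = 0.00834). Jag2 had an interaction of −1.14 ± 0.16, Sdc3 of −1.13 ± 0.15 and Cd109 of −1.12 ± 0.21. Cdkn1a was at −0.97 ± 0.16, Phgdh at 0.53 ± 0.11, Krt7 at 0.66 ± 0.08, Cdh1 at −0.38 ± 0.08 and Spp1, of the list of BACH1-activated genes, at 0.74 ± 0.09. The interactions of Hmox1 and Slc7a11 were not called, at −0.54 ± 0.22 (adjusted p = 0.151) and 0.65 ± 0.27 (adjusted p = 0.155). Without replicate 1 of sgCTRL_siFEM1B both were called (0.0319 for Hmox1, 0.0226 for Slc7a11), and likewise without replicate 2 of sgBACH1_siFEM1B (0.00383 and 0.0146). The interactions of Fem1b, at 0.15 ± 0.12 (adjusted p = 0.479), and Nfe2l2, at 0.14 ± 0.08 (adjusted p = 0.332), were not called.

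**Figure D4:**
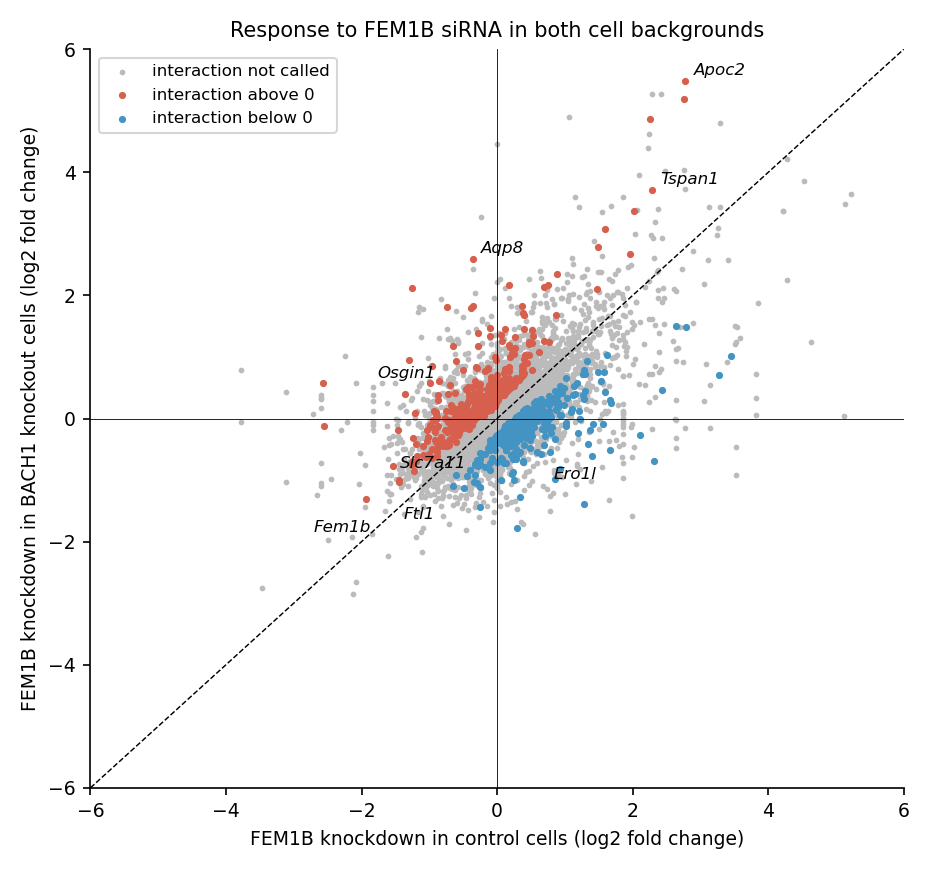
Log2 fold change with FEM1B siRNA in control cells (horizontal axis) and knockout cells (vertical axis) for each gene tested; coloured points are genes called in the interaction, and 1 gene lies outside the axes, which end at 6 on either side of 0. The 2 sets of values correlated with r = 0.628 across genes, and 807 genes were called in the interaction.

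Besides NRF2 targets, 6 lists were called in the interaction. Hypoxia targets had 7 of 16 members called below 0 (11 adjusted over the list alone), median −0.41 (adjusted p = 9.41e-07; adjusted p = 0.457 with an estimated correlation; fry adjusted p = 0.0748). ER chaperones also had 7 of 16 called below 0 (11 adjusted over the list alone), among them Hsp90b1 (−0.62 ± 0.13), Manf (−0.61 ± 0.11) and Hyou1 (−0.41 ± 0.08), with a median of −0.30 (adjusted p = 9.41e-07; adjusted p = 0.429 with an estimated correlation). Glycolysis genes had 2 of 20 called below 0 (5 adjusted over the list alone), among them Pgk1 (−0.62 ± 0.13), with a median of −0.22 (adjusted p = 0.000248; adjusted p = 0.541 with an estimated correlation; fry adjusted p = 0.125). BACH1-repressed genes had 3 of 18 called above 0 (5 adjusted over the list alone), median 0.23 (adjusted p = 0.0337; adjusted p = 0.306 with an estimated correlation), a call that ended among genes with an average log2 CPM of at least 3 (0.0685). It also ended without replicate 1 of sgCTRL_siCTRL (0.052), replicate 3 of sgBACH1_siCTRL (0.0528), replicate 1 or 2 of sgCTRL_siFEM1B (0.0618 and 0.0652) or replicate 2 of sgBACH1_siFEM1B (0.1). Mesenchymal genes had 1 of 18 called below 0 (3 below and 1 above adjusted over the list alone), median −0.20 (adjusted p = 0.0337; adjusted p = 0.429 with an estimated correlation). Fry, which asks another question, gave mesenchymal genes an adjusted p of 0.0748. The camera call ended among genes with an average log2 CPM of at least 3 (0.104). The same happened without replicate 1 of sgCTRL_siCTRL (0.052), of sgBACH1_siCTRL (0.0521) or of sgBACH1_siFEM1B (0.0537), or replicate 2 of sgCTRL_siFEM1B (0.108).

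Mitosis genes were called as a list with a median of −0.10 (adjusted p = 0.0337; adjusted p = 0.745 with an estimated correlation; fry adjusted p = 0.447), while edgeR and limma voom each called 0 of the 20 members, DESeq2 3, and 5 had an unadjusted p under 0.05 in edgeR. Adjusted over the list alone, 3 mitosis genes were called below 0. The mitosis call ended without replicate 2 or 3 of sgCTRL_siCTRL (0.0873 and 0.0501), replicate 1 of sgBACH1_siCTRL (0.0647), replicate 1 or 3 of sgCTRL_siFEM1B (0.0784 and 0.197) and replicate 1 or 3 of sgBACH1_siFEM1B (0.111 and 0.117), and the median was −0.16 without replicate 2 of sgBACH1_siFEM1B. Ferroptosis defence genes had 4 of 35 called above 0, such as Fth1 and Coq2 (0.65 ± 0.13), and Hspa5 called below 0 (5 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.0795). The ATF4 response had 2 of 25 called above and 3 called below 0 (3 and 5 adjusted over the list alone; adjusted p = 0.856), with a median of 0.14 and a mean of 0.07 while the test pointed below 0. The signs also differed for CUL2 ligase, lysosomal and interferon genes.

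Few markers of other cell types had enough counts to be kept. Of 10 fibroblast markers 3 were kept, of 11 leukocyte markers 1 (Cd68), of 7 endothelial markers 1 (Cdh5), of 9 alveolar type 2 markers 3, and of 10 airway and gut markers 3. These lists were too short to test, and respiratory genes of the mitochondrial genome were not used here. Cd68 was at 8.2 ± 1.15 CPM in control and 5.57 ± 0.459 CPM in knockout cells with control siRNA, and at 24.6 ± 4.42 and 9.45 ± 1.36 CPM with FEM1B siRNA. Cdh5 had 29 and 55 counts over the 3 control-cell libraries of each siRNA and 0 and 1 over those of knockout cells. Hnf4a, a gut-lineage factor, was higher in knockout cells by 1.31 ± 0.10 under control siRNA and 1.54 ± 0.10 under FEM1B siRNA. The fibroblast marker Col1a1 was lower, at −1.42 ± 0.10 and −0.93 ± 0.10. The other kept fibroblast markers had few counts and went opposite ways. Summed over each group, Col1a2 had 57 counts in control and 21 in knockout cells with control siRNA, and 50 and 7 with FEM1B siRNA. Pdgfra had 5 and 34 with control siRNA, and 26 and 40 with FEM1B siRNA.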

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

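The tests of scattered changes, a fixed line difference, lost chromosome copies and leukocyte RNA were chosen only after the result was seen. So were those of differences between the cell lines and of single libraries, and the comparison of splits by how they moved labels. The other tests here were chosen before. The chromosome-wide shifts and the pooling of the hypoxia and ER chaperone lists were themselves taken from these data.

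The effect of FEM1B siRNA differed between control and knockout cells for the genes and lists that follow, by the test of the interaction itself in edgeR and, for lists, camera. These calls compare 1 line of each guide, so an effect of BACH1 cannot be told apart from other differences between the lines. Positive log2 interactions, meaning a higher value of the siRNA effect in knockout cells, were measured for Aqp8 (2.94), Apoc2 (2.71), Cldn2 (2.55), Ifitm1 (1.58), Hsd17b14 (1.55), Acaa1b (1.46), Ifitm3 (1.45), Osgin1 (1.11), Gsta4 (0.94), Spp1 (0.74), Gstm1 (0.70), Krt7 (0.66), Fth1 (0.65), Coq2 (0.65), Idh1 (0.56) and Phgdh (0.53). Negative interactions were measured for Ero1l (−1.23), Jag2 (−1.14), Sdc3 (−1.13), Cd109 (−1.12), Cdkn1a (−0.97), Hspa5 (−0.83), Ndrg1 (−0.83), Hsp90b1 (−0.62), Pgk1 (−0.62), Manf (−0.61), Hyou1 (−0.41) and Cdh1 (−0.38). Each of these calls held without any of the 12 libraries. Among lists the median interaction was 0.24 for NRF2 targets and 0.23 for BACH1-repressed genes. It was −0.41 for hypoxia targets, −0.30 for ER chaperones, −0.22 for glycolysis, −0.20 for mesenchymal genes and −0.10 for mitosis genes. With an estimated correlation the call of NRF2 targets held (adjusted p = 0.0200). The others were lost, with adjusted p = 0.306 with an estimated correlation for BACH1-repressed genes, 0.457 for hypoxia targets, 0.429 for ER chaperones, 0.541 for glycolysis, 0.429 for mesenchymal genes and 0.745 for mitosis genes. Of the 20 mitosis genes edgeR called 0, DESeq2 3 and limma voom 0, and 5 had an unadjusted p under 0.05. Fry gave an adjusted p of 0.0748 for hypoxia targets and for mesenchymal genes, 0.125 for glycolysis and 0.447 for mitosis genes. The call of BACH1-repressed genes also ended without sgCTRL_siCTRL 1 (0.052), sgBACH1_siCTRL 3 (0.0528), sgCTRL_siFEM1B 1 or 2 (0.0618 and 0.0652) and sgBACH1_siFEM1B 2 (0.1). That of mesenchymal genes ended without sgCTRL_siCTRL 1 (0.052), sgBACH1_siCTRL 1 (0.0521), sgCTRL_siFEM1B 2 (0.108) and sgBACH1_siFEM1B 1 (0.0537). That of mitosis genes ended without sgCTRL_siCTRL 2 or 3 (0.0873 and 0.0501), sgBACH1_siCTRL 1 (0.0647), sgCTRL_siFEM1B 1 or 3 (0.0784 and 0.197) and sgBACH1_siFEM1B 1 or 3 (0.111 and 0.117), and its median was −0.16 without sgBACH1_siFEM1B 2.

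The rule for naming genes took 59 genes called in the interaction, of which 29 lost the call without at least 1 library and 30 kept it without each. Of the 59 genes 37 are given here and 22 are not. The genes given were chosen after these results were seen and favour calls that held, so their share of stable calls overstates that of the rule's genes. Of the 37 given, 9 had calls that ended without single libraries, here with the adjusted p without each. Tspan1 had an interaction of 1.43 (adjusted p = 0.0465), called neither in limma voom (0.0986), nor with RLE factors (0.05), nor without replicates 1, 2 or 3 of sgCTRL_siCTRL (0.0751, 0.0794 and 0.0655), 1, 2 or 3 of sgBACH1_siCTRL (0.0867, 0.0523 and 0.2), 2 or 3 of sgCTRL_siFEM1B (0.0831 and 0.0573) and 1 or 3 of sgBACH1_siFEM1B (0.122 and 0.0962). Pgf had −1.33 (0.0286), lost in DESeq2 (0.085) and without sgCTRL_siCTRL 2 or 3 (0.0531 and 0.0782), sgBACH1_siCTRL 1 or 3 (0.0704 and 0.0731), sgCTRL_siFEM1B 2 (0.0669) and sgBACH1_siFEM1B 1 or 3 (0.0867 and 0.0923). Tnfrsf11b had −1.16 (0.0289), lost in limma voom (0.0806) and without sgCTRL_siCTRL 1 or 3 (0.0668 and 0.099), sgBACH1_siCTRL 1 or 3 (0.0573 and 0.0676), sgCTRL_siFEM1B 2 (0.0957) and sgBACH1_siFEM1B 1 or 3 (0.063 and 0.0642). Selenbp1 had −1.09 (0.0306), lost in DESeq2 (0.0764) and without sgCTRL_siCTRL 1, 2 or 3 (0.0542, 0.0624 and 0.0705), sgBACH1_siCTRL 1 or 3 (0.0799 and 0.0745), sgCTRL_siFEM1B 2 (0.0655) and sgBACH1_siFEM1B 1 or 3 (0.0899 and 0.0962). Atp7b had −1.08 (0.0295), lost without sgCTRL_siCTRL 2 or 3 (0.0718 and 0.0615), sgBACH1_siCTRL 1 or 3 (0.0733 and 0.0791), sgCTRL_siFEM1B 2 (0.0762) and sgBACH1_siFEM1B 1 or 3 (0.0867 and 0.0901). Gclm had 0.33 (0.0318), lost without sgCTRL_siCTRL 2 or 3 (0.0666 and 0.0782), sgBACH1_siCTRL 1, 2 or 3 (0.0657, 0.0622 and 0.0703), sgCTRL_siFEM1B 1 or 2 (0.056 and 0.0699) and sgBACH1_siFEM1B 3 (0.0565). Prdx6 had 0.32 (0.0314), lost with the replicate block (0.0508) and without sgCTRL_siCTRL 1 (0.0784), sgBACH1_siCTRL 1 or 3 (0.0896 and 0.0862), sgCTRL_siFEM1B 1 or 2 (0.0507 and 0.0533) and sgBACH1_siFEM1B 1 or 3 (0.113 and 0.0598). Aldoc had −0.47 (0.0289), lost without sgCTRL_siCTRL 2 or 3 (0.0618 and 0.0636), sgBACH1_siCTRL 1, 2 or 3 (0.0531, 0.051 and 0.0745), sgCTRL_siFEM1B 2 (0.0559) and sgBACH1_siFEM1B 1 or 3 (0.0882 and 0.0939). Tgfb1 had −0.30 (0.0225), lost without sgCTRL_siCTRL 3 (0.0676), sgBACH1_siCTRL 1 (0.0797), sgCTRL_siFEM1B 2 (0.0533) and sgBACH1_siFEM1B 1 (0.0854).

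Whole chromosomes shifted between knockout and control cells, with a median of 0.44 on chromosome 19. Removing the trend with GC content and gene length left 98.8% of the SD of the chromosome medians, which argues against that bias as the cause. The SD of 0.169 lay above the highest of 1000 shuffles of blocks of 50 neighbouring genes, 0.0778, which argues against scattered changes. The medians under the 2 siRNAs, which share no library, correlated with r = 0.991 across the 20 chromosomes, consistent with a difference fixed in the cell line, such as copy number. Copy number was not measured and 1 knockout line was sequenced, so loss of BACH1 as the source stays open and untested.

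All 21 interferon genes were lower in knockout cells, median −3.50. The chromosome medians of this contrast ran from −0.28 to 0.44, and with them removed the median of the list was −3.55. Whole-chromosome shifts of that size are too small for the fall of these genes. The outcome of the removal was thus fixed in advance, and loss of a smaller stretch was not tested. The median leukocyte marker reached 0% of the level of the interferon list in control cells, 14.4 CPM; Lyz2 had 12 counts and Tyrobp 0 over the 6 control-guide libraries. The exception was Cd68, with 2014 counts, at 8.2 CPM in control cells with control siRNA and 24.6 CPM with FEM1B siRNA, where the highest of the other 10 markers was at 0.128 and 0.243 CPM. Leukocyte RNA brings its abundant transcripts together, so the near absence of the other 10 argues against it, and the level of Cd68 on its own was not explained. A difference between the 2 cell lines other than BACH1 cannot be told apart from loss of BACH1, since 1 knockout line was named. Genes with 0 counts in all 6 control-guide libraries and at least 10 in each knockout library numbered 32, and the reverse 2.

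The hypoxia and ER chaperone lists together had 30 of 32 genes, called or not, with an interaction below 0, median −0.38. Leaving out any 1 library left the median at −0.32 or lower, the weakest without replicate 1 of sgBACH1_siFEM1B, which argues against a single library. With the GC and length trend removed it was −0.34, which argues against that bias. Culture state, such as density or medium, may differ between groups: the mean log2 CPM of these genes spanned 0.360 within 1 group, where replicate 2 of sgBACH1_siFEM1B was at 7.63 and the others at 7.27 and 7.29. No label separates culture state from the groups, so culture state, other differences between the lines and an effect of BACH1 cannot be told apart.

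For each contrast of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For knockout with control siRNA, 1 split gave as many genes as the real 6702, the real one, and the highest other gave 0; for lists 10 splits gave as many as the real 1, and the highest other gave 5. For FEM1B siRNA in control cells 1 split gave as many as 5981 genes, with 0 the highest other, and 1 as many as 10 lists, with 7 the highest other. For FEM1B siRNA in knockout cells 1 split gave as many as 5539 genes, with 0 the highest other, and 2 as many as 7 lists, with 9 the highest other. For knockout with FEM1B siRNA 1 split gave as many as 7246 genes, with 11 the highest other, and 8 as many as 3 lists, with 11 the highest other.

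For the interaction chance could not be excluded by this count: 9 of 100 splits gave as many genes as the real 807, with 7303 the highest other, and 28 of 100 gave as many as the real 7 lists, with 13 the highest other. A split with several times the real count points to a structure of the samples, here the shared effect of FEM1B siRNA. The other 8 of the 9 moved siRNA labels unequally in the genotypes, which turns that shared effect into an interaction. Among the 39 other splits that moved labels equally, the highest count of genes was 0, and 4 gave as many lists, the highest 11. These splits mix both siRNAs within a group, so the siRNA effect adds to the spread and few gene calls can arise. Their count of genes therefore does not exclude chance for the real 807.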

How the results depend on the processing

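Removal of the chromosome medians was chosen only after the result was seen; the other settings were planned. Counts of called genes stayed within 1.5 times in each contrast between groups under DESeq2, limma voom, other factors, no filter, a log2 CPM minimum, the block, the 6 libraries compared, removal of chromosome medians and each library left out. Removal of chromosome medians shifts both knockout groups alike, so it tests the knockout contrasts alone and cannot change those of FEM1B siRNA. A fold of at least 2 gave 1244 and 1320 genes for knockout with control and FEM1B siRNA, and 541 and 507 for FEM1B siRNA in control and knockout cells, fewer by construction. For the interaction that fold gave 90, an adjusted p under 0.01 gave 175 and no filter 1393. Leaving out 1 library gave 297 to 1859, the lowest without replicate 1 and the highest without replicate 2 of sgBACH1_siFEM1B; replicate 3 gave 299. Without sgBACH1_siCTRL 1 or 3 it was 298 and 305, without sgCTRL_siCTRL 3 386, and without sgCTRL_siFEM1B 2 396; the cause was not tested.

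Of 130 list tests 28 were called, 1 with an estimated correlation, 59 with directional fry and 121 with mixed fry, which ask other questions. The correlation of the knockdown contrasts was 0.734 among genes with an average log2 CPM of at least 3, which drops low genes, and 0.561 to 0.632 without each library. That of knockout and knockdown was 0.0949 to 0.189 without each library; the cause was not tested.

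Of 534 values of named genes DESeq2 ended 14 calls, limma voom 4, RLE factors 7 and removal of chromosome medians 25 with the direction kept. That removal also turned Ndufv1 to −0.0831 (adjusted p = 0.215) and Sufu to −0.11 (0.217) in knockout cells with control siRNA and Keap1 to −0.0866 (0.313) with FEM1B siRNA, which ended their calls. It turned Sufu to −0.18 with FEM1B siRNA, called below 0 (0.0438), and Nfe2l2, not called, to 0.0661 with control siRNA, because it subtracts the median of their chromosome. With FEM1B siRNA it brought Nfe2l2, not called in the main fit, to 0.206 in knockout against control cells, called above 0 (0.00897). Samples with the same replicate number did not deviate together: 0 of 18 such pairs correlated over 0.1, from −0.115 to 0.0788, and 1 library was closest to its own number. With the replicate block 6488, 5749, 5298 and 7031 genes were called in the contrasts between groups, 603 in the interaction and 27 lists; it ended 11 calls of named genes. At this depth the interaction recovered 65.7% of simulated 1.5-fold changes, in simulations with 200 changed genes.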

Other observations

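The tests of the NRF2 and BACH1 hypotheses were both chosen only after the result was seen.

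A hypothesis is that the lower NRF2 targets with FEM1B siRNA in control cells follow from the lower Nfe2l2 transcript alone. The list as fixed includes Nfe2l2 itself and Keap1, so its counts are not wholly separate from the proposed cause. By camera, that call of the list was lost with an estimated correlation (adjusted p = 0.137). In knockout cells the list was not called (adjusted p = 0.994). Nfe2l2 fell in both genotypes, and its interaction was not called (adjusted p = 0.332). The median of the targets was −0.18 in control cells and 0.02 in knockout cells, 27 of 30, called or not, had an interaction above 0, and the list was called with an estimated correlation (adjusted p = 0.0200). In knockout cells the fall of Nfe2l2 thus came without a called fall of the list. The cell lines may differ in how far these genes depend on Nfe2l2, and an uncalled interaction does not show equal falls of Nfe2l2. The test therefore cannot decide whether the transcript is the whole cause in control cells. Levels of the NRF2 and BACH1 proteins were not analysed here.

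A related hypothesis is that FEM1B siRNA lowers BACH1-repressed genes through BACH1, which may give a smaller fall without it. This list shares many members with the NRF2 targets, so the tests of the hypotheses are not independent. Knockout itself, under control siRNA, had 3 of the 18 genes called higher and 10 lower (median −0.26). The list is therefore an uncertain measure of BACH1 activity in these lines. By camera, the fall of BACH1-repressed genes in control cells was no longer called with an estimated correlation (adjusted p = 0.175). In knockout cells they were not called as a list (adjusted p = 0.433), with 8 of 18 called lower and 5 higher. Those called lower included Ftl1, Slc7a11 and Hmox1, whose fall there came despite the knockout. The medians were −0.32 in control cells and −0.12 in knockout cells, and the median interaction was 0.23, with 12 of 18 genes, called or not, above 0. The call of the list in the interaction was lost with an estimated correlation (adjusted p = 0.306), so the test leaves the hypothesis open. Hmox1 went the other way, with an uncalled interaction of −0.54 ± 0.22 (adjusted p = 0.151); that interaction was called without replicate 1 of sgCTRL_siFEM1B (0.0319) or replicate 2 of sgBACH1_siFEM1B (0.00383).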
